A study of Mus musculus with 34 samples.

How the data were processed

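RNA sequencing was done on 34 libraries from male C57BL/6J mice at postnatal day 56. The libraries came from 3 brain regions, prefrontal cortex (PFC), hippocampus and striatum, of Myt1l heterozygotes and wild-type mice. The labels name total RNA and a TruSeq RNA library kit, give no treatment, do not describe the Myt1l allele, and do not say whether libraries came from separate animals. The deposited table holds a signal value per gene and library, which the authors call DESeq counts in the file name; the values are read counts divided by a scaling factor and are called normalized counts here. They are not whole numbers, so they were not treated as raw counts, which had been assumed when the tests were chosen. For the deposited table, the authors name Salmon 1.1.0, R 3.6.2, DESeq2 1.26.0 and the genome build GRCm38, without a role or an order for any of them. The table lists 18548 genes, of which 18533 identifiers matched the annotation used for symbols and positions and 15 did not. Every gene reached at least 10.2 in some library, so genes below a level are absent from the table.

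The sum of the normalized counts per library was 25786041 to 29798959. The depth before scaling is not given. The low values of each library clustered at steps of 0.744 to 1.22 normalized counts, taken as the value of 1 read, with a second cluster at double that step in 34 of 34 libraries. On this reading the libraries held 23989000 to 39310000 reads, an estimate from the values and not a deposited figure. No interval for counting error was computed, since whole reads could not be obtained back. Precision is given as the spread between libraries.

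Values were transformed to log2(value + 1). Within each region, genes with a mean value of at least 10 were tested for heterozygote against wild type with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend and the robust option), 2-sided, with Benjamini-Hochberg adjustment over all genes tested at 0.05 and no fold threshold. The edgeR test chosen for raw counts was not used, by a rule fixed beforehand for scaled values. The difference of the genotype effects between regions was tested as an interaction in 1 model of all 34 libraries with the 6 groups as means. Gene lists were tested with camera from limma with a preset correlation between genes of 0.01, adjusted over the 35 lists of a region. Camera ran on log2(value + 1) and not on log2 CPM as first written. Beside it stand camera with an estimated correlation, fry, and an exact permutation test of the library means of each list. SE is the standard error from limma for a gene and from the library means for a list. Other tables were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

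The comparisons by region, the 35 lists (14 of them markers of cell types or regions), the rule for named genes and most alternatives were chosen before the data were examined. Several lists share members. The named genes were Myt1l, then in each region up to 10 genes in each direction past the threshold, or, where fewer than 5 passed in a direction, the 5 with the smallest p in that direction, said not to pass. For a list called by camera with fewer than 2 members past the threshold, the 2 members with the smallest p were named. For each pair of regions the 2 genes with the smallest p for the difference of effects were named where none passed. Other genes were named because they passed over a list alone or in a comparison added later. Adjustment over a list alone covers the members of that list and not the 35 lists of a region, so genes can pass it by chance. Some genes that these rules pick are not reported here.

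Column names carry a code, and 12 codes occur, of which 10 recur in 3 regions and 2 in 2 regions. The labels do not say that a code marks an animal. The code 31-67M stands on a wild-type PFC library (replicate 6) and on heterozygote libraries of hippocampus (replicate 1) and striatum (replicate 1); the labels were followed. The first part of the code was read as a cohort: 5 libraries carry 31, 23 carry 35 and 6 carry 37. A comparison of the genotypes averaged over the regions and comparisons of the regions within wild type were added after seeing the data. The average used the model of all 34 libraries, and the region comparisons a model of the 18 wild-type libraries, both with the code as a random block. The average had 13 units, 31-67M divided by genotype, with a correlation within a unit of 0.0429.

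The tests were tested on simulated data: normal noise with the spread of each gene was drawn around wild-type means, independently between genes, and 100 genes each were changed by 0.5 or 1 on the log2 scale in simulated heterozygotes. The PFC, hippocampus and striatum tests recovered 74%, 62% and 62% of the genes changed by 0.5 and 84%, 81% and 80% of those changed by 1. The average over regions recovered 78% and 96%, and the PFC against hippocampus interaction 38% and 69%. Unchanged genes made up 8 of 166 calls in PFC, 10 of 153 in hippocampus, 4 of 146 in striatum, 12 of 186 in the average and 8 of 115 in the interaction, in 1 simulation of each; the average was fitted there without the block. A list of 48 genes shifted by -0.1 was called in each region, with 1 unshifted list called in striatum. The shifted list, oxidative phosphorylation genes, had an estimated correlation of 0.52 in PFC and 0.27 in hippocampus in the real data. The simulation drew genes independently, so it does not show how often camera calls real lists by chance.

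Alternatives were other scalings, filters, pseudocounts, a fit of all libraries together, a replicate block, each library left out in turn, and, added after seeing the data, the cohorts. The replicate block kept only numbers present in both genotypes, so its PFC and hippocampus fits lacked wild-type replicate 6. DESeq2, limma-voom and surrogate variables were not run. No library was left out of the main fits. During exploration the heterozygote libraries were once divided by whether Hist2h2aa2 was at 0 and compared; that comparison follows a measured outcome and is not used.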

Results

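Gene expression was measured by RNA sequencing in 3 brain regions of adult Myt1l heterozygous and wild-type mice. Myt1l encodes a zinc finger transcription factor of neurons, and Myt1 and St18 are the other members of its family. PFC gave 5 heterozygote and 6 wild-type libraries, hippocampus 5 and 6, and striatum 6 and 6. The normalized counts per library summed to 29158793 to 29761281 in PFC heterozygotes and 29092563 to 29798959 in PFC wild type. They summed to 27160218 to 28002710 in hippocampus heterozygotes and 27469738 to 27871456 in hippocampus wild type. In striatum they summed to 25786041 to 27226962 in heterozygotes and 26103069 to 27313394 in wild type. The reads per library were estimated at 23989000 to 39310000.

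Myt1l RNA was not lower in the heterozygotes than in wild type in any of the 3 regions. Myt1l (ENSMUSG00000061911, GRCm38 chromosome 12, 29528384 to 29923213) was at 6820 ± 456 normalized counts (SD, n = 5) in PFC heterozygotes and 6650 ± 842 (SD, n = 6) in wild type. It was at 6896 ± 385 (SD, n = 5) against 6216 ± 594 (SD, n = 6) in hippocampus, and at 8162 ± 954 (SD, n = 6) against 7675 ± 552 (SD, n = 6) in striatum. The log2 differences were 0.04 (SE 0.08; limma adjusted p = 0.988), 0.15 (SE 0.06; adjusted p = 0.719) and 0.08 (SE 0.07; adjusted p = 0.915). The 95% intervals reached down to -0.12 in PFC, 0.03 in hippocampus and -0.07 in striatum, so the decrease of 1 that a loss of all RNA from 1 of a pair of equal alleles would give lies outside each of them. Single libraries spanned 6388 to 7525 in PFC heterozygotes and 5578 to 7992 in PFC wild type, and without PFC wild-type replicate 1 the difference in PFC Myt1l level was -0.00543. Within the libraries whose code begins with 35, the striatum difference was -0.012.

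**Figure D1:**
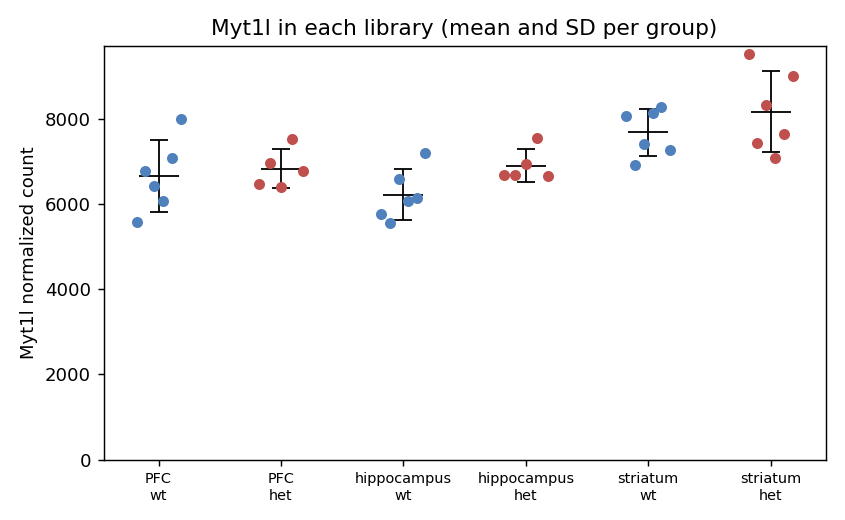
Myt1l normalized counts (vertical axis, starting at 0) in each of the 34 libraries by region and genotype; points are libraries, long bars are group means and whiskers are the SD. Heterozygote libraries sit between 6388 and 7525 in PFC, 6645 and 7550 in hippocampus and 7064 and 9505 in striatum, overlapping the wild-type libraries in each region.

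The PFC comparison asked which genes differ between heterozygotes and wild type in prefrontal cortex. No gene passed the adjusted threshold, and the genes with the smallest p in each direction are given as values. Sox13, a SOX family transcription factor, was at 276 ± 19.4 normalized counts (SD, n = 5) in heterozygotes and 203 ± 13.5 (SD, n = 6) in wild type, a log2 difference of 0.44 (SE 0.08). Tgtp1, an interferon-inducible GTPase, had a log2 difference of 1.23 (SE 0.25), and Fam228b one of 0.74 (SE 0.16). Ntsr2, a neurotensin receptor, and Katna1, the catalytic subunit of katanin, had values of 0.20 (SE 0.04) and 0.35 (SE 0.08). On the lower side stood Abcb8, a mitochondrial transporter, at -0.40 (SE 0.08), Mycbpap at -1.03 (SE 0.22) and Npnt, which encodes the matrix protein nephronectin, at -0.29 (SE 0.06). Gm1673 was at -0.43 (SE 0.10) and Bphl at -0.35 (SE 0.08). Each of the 5 higher genes was above the wild-type mean in 5 of 5 heterozygote libraries, and each of the 5 lower genes in 0 of 5. Selection by the smallest p favours such separation, so it is no separate support.

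In limma, 0 of 16667 genes tested in PFC passed, and 833 had an unadjusted p under 0.05 where chance gives 833; the smallest adjusted p was 0.618. The median 95% interval of a gene reached 0.19 to either side on the log2 scale, and 92.9% of genes had an interval within 1 of 0. Within the libraries whose code begins with 35, 1 gene passed, Mycbpap (log2 difference -1.43, SE 0.19), and without heterozygote replicate 2 there were 2, Tgtp1 and Gm29216.

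Of the 35 gene lists, 4 were called in PFC by camera, 1 higher and 3 lower in heterozygotes, without any member past the threshold over all genes and with 0 members adjusted over the list alone. Oxidative phosphorylation genes had the smallest p: 38 of 48 members lay below 0, with a mean log2 difference of -0.06 (SE 0.05) and adjusted p = 5.8e-05, or adjusted p = 0.974 with an estimated correlation. Without PFC wild-type replicate 1 that call was lost (mean -0.02, adjusted p = 0.222). This library stood apart from the other 5 of its group in cell type markers, at a mean log2 of 10.8 for oligodendrocyte and myelin genes, where the others averaged 11.3, and 8.96 for meningeal fibroblast and collagen genes, where they averaged 8.47. Its named members were Cox5b, a cytochrome c oxidase subunit, at -0.17 (SE 0.05), and Uqcrq, a complex III subunit, at -0.23 (SE 0.07). Among cytosolic ribosomal protein genes 36 of 47 members lay below 0 (mean -0.03, SE 0.05; adjusted p = 0.0051, and adjusted p = 0.974 with an estimated correlation), with Rps19 at -0.15 (SE 0.08). The direction of the ribosomal list turned without wild-type replicate 1 (mean 0.0041, adjusted p = 0.423), and the call was lost without heterozygote replicate 3 (adjusted p = 0.133) or 4 (mean -0.01, adjusted p = 0.191). Its mean was -0.06 without wild-type replicate 6, the only PFC library whose code begins with 31. The fit with a replicate block also lacked that library and gave the same mean of -0.06. The mean of the ribosomal list was -0.05 without heterozygote replicate 2 and -0.07 within the libraries whose code begins with 35. Of the heat shock and unfolded protein response genes, 19 of 22 lay below 0 (mean -0.07, SE 0.04; adjusted p = 0.023, and adjusted p = 0.974 with an estimated correlation). Hspa1b, an inducible HSP70, was at -0.33 (SE 0.13), and Hspa5, the chaperone BiP, at -0.13 (SE 0.06). The heat shock call was lost in 7 of 11 fits that left out 1 library: heterozygote replicates 1, 3 and 4 (adjusted p = 0.138, 0.133 and 0.323; mean -0.04 for the last) and wild-type replicates 1, 2, 5 and 6 (adjusted p = 0.0551, 0.078, 0.0586 and 0.0659). The endothelial and mural markers had 14 of 17 members above 0 (mean 0.08, SE 0.06; adjusted p = 0.0051, and adjusted p = 0.974 with an estimated correlation), with Myl9, a smooth muscle myosin light chain, at 0.22 (SE 0.08) and Pltp, a phospholipid transfer protein, at 0.16 (SE 0.06). The endothelial call was lost without wild-type replicate 2 (mean 0.06, adjusted p = 0.0839) or heterozygote replicate 1 (mean 0.04, adjusted p = 0.243). PFC heterozygote replicate 1 stood apart from the other 4 of its group in this list, at a mean log2 of 9.79 where the others averaged 9.57.

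In hippocampus, the same question gave small p values at Cacna1g, the T-type calcium channel Cav3.1, and at Htr1a, the serotonin 1A receptor; neither passed the threshold. Cacna1g was at 2665 ± 200 normalized counts (SD, n = 5) in heterozygotes and 2119 ± 68.4 (SD, n = 6) in wild type (log2 difference 0.33, SE 0.05; adjusted p = 0.0701). Htr1a was at 728 ± 74.5 (SD, n = 5) and 965 ± 62.3 (SD, n = 6), a log2 difference of -0.41 (SE 0.07; adjusted p = 0.0956). Cdh9, a cadherin, was at -0.33 (SE 0.06), Nptn, the adhesion protein neuroplastin, at -0.30 (SE 0.05) and Hax1 at -0.32 (SE 0.06). On the higher side, Leng8 was at 0.16 (SE 0.03), C78859 at 0.22 (SE 0.05), Gm8797 at 1.29 (SE 0.20) and the histone H2A gene Hist2h2aa1 at 1.77 (SE 0.29). The assignment of reads to Gm8797 and Hist2h2aa1 is uncertain, since related sequences can share reads. The higher genes named were above the wild-type mean in 5 of 5 heterozygote libraries and the lower genes named in 0 of 5. As in PFC, the choice by smallest p favours this.

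By limma 0 of 16820 genes passed in hippocampus; 1145 had an unadjusted p under 0.05 where chance gives 841, of which 492 were higher and 653 lower. The count was 6 without the libraries whose code begins with 31 (Cacna1g, Htr1a, Brca2, Gpatch11, Hist2h2aa1 and Hist2h2aa2), 2 within those beginning with 35, and 4 without heterozygote replicate 1. It was 2 without wild-type replicate 2. It was 1 without wild-type replicate 3 or 6, with equal library totals or with the cohort as a covariate. It was also 1 with a replicate block, a fit that lacked wild-type replicate 6 as well.

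Camera called 3 lists in hippocampus, and 7 entries (a gene in 2 lists counting in both) passed when adjusted over the list alone, against 0 over all genes. The adjustment over a list alone does not correct for the 35 lists. The presynaptic genes had 20 of 28 members below 0 (mean -0.03, SE 0.03; adjusted p = 0.0155, and adjusted p = 0.994 with an estimated correlation). Complexin 1 (Cplx1, -0.15, SE 0.03) and synaptotagmin 1 (Syt1, -0.11, SE 0.03), both of the release machinery, passed over that list alone. The presynaptic call was lost without heterozygote replicate 3 (mean -0.01, adjusted p = 0.465) or 4 (mean -0.02, adjusted p = 0.227), without wild-type replicate 2 (adjusted p = 0.0532) or 6 (adjusted p = 0.115), and with a replicate block (adjusted p = 0.0729); without heterozygote replicate 2 the mean was -0.06. Of the oxidative phosphorylation genes 31 of 48 lay below 0 (mean -0.04, SE 0.03; adjusted p = 0.0155, and adjusted p = 0.994 with an estimated correlation); Cox5b, at -0.24 (SE 0.05), passed over the list alone, and Uqcrq was at -0.18 (SE 0.05). The call of the oxidative phosphorylation genes was lost without heterozygote replicate 2 (mean -0.03, adjusted p = 0.201) or 5 (mean -0.02, adjusted p = 0.226), without wild-type replicate 6 (adjusted p = 0.148), with a replicate block (adjusted p = 0.178) and within the libraries whose code begins with 35 (mean -0.02, adjusted p = 0.461). Markers of thalamus and other neighbouring regions had 11 of 12 members above 0 (mean 0.40, SE 0.30; adjusted p = 0.0155, and adjusted p = 0.994 with an estimated correlation). Its named members were Six3, a forebrain homeobox gene, at 72.7 ± 53.3 (SD, n = 5) against 19.7 ± 4.91 (SD, n = 6), and Rora, a nuclear receptor, at 0.22 (SE 0.13). The call of this list was lost without heterozygote replicate 4 (mean 0.25, adjusted p = 0.238) or 5 (mean 0.25, adjusted p = 0.195) or wild-type replicate 6 (mean 0.29, adjusted p = 0.115), and its mean was 0.63 without heterozygote replicate 1. The autism risk genes Phf21a (0.31, SE 0.07) and Satb1 (-0.19, SE 0.05) passed over their list alone, a list that was not called. Without wild-type replicate 6, 0 lists were called by camera. The fit with a replicate block also lacked wild-type replicate 6, so these settings are not independent. This library stood apart in the choroid plexus and ependymal markers, at a mean log2 of 6.80 where the other 5 averaged 8.96, and in the blood cell genes, at 8.24 against 7.95. The choroid plexus and ependymal markers had 15 of 15 members above 0 in heterozygotes (mean 0.22, SE 0.65; adjusted p = 0.258) and were not called.

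In striatum, the genes with the smallest p on the higher side included Snrnp70, a protein of the U1 spliceosomal particle, and Firre, a long noncoding RNA of the X chromosome; neither passed. Snrnp70 was at 9186 ± 431 normalized counts (SD, n = 6) in heterozygotes and 7837 ± 395 (SD, n = 6) in wild type (log2 difference 0.23, SE 0.04). Firre was at 0.22 (SE 0.04), Ppox, an enzyme of heme synthesis, at 0.28 (SE 0.06) and Leng8 at 0.18 (SE 0.04). Rpl14-ps1, a ribosomal protein pseudogene whose reads can come from its parent gene, was at 234 ± 215 (SD, n = 6) in heterozygotes and listed at 0 in the 6 wild-type libraries. Lower values were found at Ppp6c, a phosphatase catalytic subunit (-0.22, SE 0.04; adjusted p = 0.441), Nrtn, the growth factor neurturin (-1.13, SE 0.21), and Nptn (-0.23, SE 0.05). Ccdc130 was at -0.57 (SE 0.12) and Timm13, a mitochondrial import protein, at -0.26 (SE 0.06). Each lower gene was above the wild-type mean in 0 of 6 heterozygote libraries. The higher genes were so in 6 of 6, except Rpl14-ps1 in 5. Here too the choice by smallest p favours such separation.

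Limma passed 0 of 17054 genes in striatum, with 1004 at an unadjusted p under 0.05 where chance gives 853. The count was 1 (Hist2h2aa1) without the libraries whose code begins with 31, 2 within those beginning with 35 and 1 (Rpl14-ps1) without heterozygote replicate 2.

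Striatum had 7 lists called by camera, 4 higher and 3 lower; 7 entries (6 genes, Penk standing in 2 lists) passed when adjusted over the list alone, against 0 over all genes. The MYT family had all 3 members above 0 (mean 0.21, SE 0.04; adjusted p = 0.0073, and adjusted p = 0.275 with an estimated correlation; fry adjusted p = 0.016). Myt1 was at 646 ± 19.9 normalized counts (SD, n = 6) against 553 ± 80.5 (SD, n = 6), and St18 at 519 ± 100.3 (SD, n = 6) against 412 ± 49.1 (SD, n = 6); both passed over the list alone. Within the libraries whose code begins with 35 the family was not called (adjusted p = 0.0825). In PFC and hippocampus the family was not called, with means of -0.04 (SE 0.13) and 0.05 (SE 0.09). St18 was at -0.18 (SE 0.25) and -0.08 (SE 0.19) there, and Myt1 at 0.03 (SE 0.19) and 0.07 (SE 0.09). Medium spiny neuron markers had 13 of 16 members below 0 (mean -0.11, SE 0.11; adjusted p = 0.0068, and adjusted p = 0.890 with an estimated correlation). The opioid peptide precursor Penk, at 12250 ± 2197 (SD, n = 6) against 15768 ± 1211 (SD, n = 6), passed over that list and over the neuropeptide list alone. Ppp1r1b, which encodes DARPP-32, was at -0.22 (SE 0.09). The call of the medium spiny neuron markers was lost without heterozygote replicate 2 (mean -0.07, adjusted p = 0.129) or 4 (mean -0.06, adjusted p = 0.133); the mean was -0.18 without replicate 6 and -0.22 within the libraries whose code begins with 35.

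The other 5 lists that camera called in striatum, none of them with an estimated correlation, were of glia, meninges and the cell cycle. Of the oligodendrocyte and myelin genes, 16 of 19 lay above 0 (mean 0.04, SE 0.06; adjusted p = 0.0089, and adjusted p = 0.890 with an estimated correlation), with Cldn11 at 0.10 (SE 0.05) and Myrf at 0.10 (SE 0.06). This call was lost without heterozygote replicate 3 (mean 0.02, adjusted p = 0.315) or wild-type replicate 1 (mean 0.0087, adjusted p = 0.372). The mean of these genes was 0.08 without heterozygote replicate 1, 0.07 without wild-type replicate 2 or 6 and 0.09 within the libraries whose code begins with 35. Of the oligodendrocyte precursor markers, 9 of 12 did (mean 0.06, SE 0.03; adjusted p = 0.0216, and adjusted p = 0.700 with an estimated correlation), with Neu4 at 0.21 (SE 0.08) and Enpp6 at 0.19 (SE 0.09). The precursor call was lost without heterozygote replicate 5 (adjusted p = 0.0744), wild-type replicate 1 (adjusted p = 0.231) or 5 (adjusted p = 0.125), without the libraries whose code begins with 31 (adjusted p = 0.0801) and within those beginning with 35 (adjusted p = 0.064). Microglia markers had 14 of 16 members below 0 (mean -0.08, SE 0.05; adjusted p = 0.0068, and adjusted p = 0.890 with an estimated correlation), among them the complement genes C1qb (-0.23, SE 0.07) and C1qa (-0.16, SE 0.07). Their call was lost without wild-type replicate 1 (adjusted p = 0.0725) or 4 (mean -0.05, adjusted p = 0.0586) and within the libraries whose code begins with 35 (adjusted p = 0.145). Meningeal fibroblast and collagen genes had 14 of 15 below 0 (mean -0.30, SE 0.14; adjusted p = 7.1e-05, and adjusted p = 0.700 with an estimated correlation). Decorin (Dcn, -0.37, SE 0.10) passed over that list alone, and Aldh1a2, a retinoic acid synthesis enzyme, was at -0.83 (SE 0.27). Cell cycle genes had 12 of 13 above 0 (mean 0.36, SE 0.17; adjusted p = 0.0021, and adjusted p = 0.700 with an estimated correlation). Cyclin B1 (Ccnb1), at 32.9 ± 6.89 (SD, n = 6) against 17.7 ± 4.86 (SD, n = 6), passed over that list alone, and Hmgb2 was at 0.94 (SE 0.35). Within the libraries whose code begins with 35, the meningeal list (mean -0.17, adjusted p = 0.0765) and the cell cycle list (mean 0.18, adjusted p = 0.205) were not called. Th, the tyrosine hydroxylase gene of dopamine synthesis, was at 0.40 (SE 0.10) and passed over the neighbouring region markers alone, a list that was not called. The number called was 13 without heterozygote replicate 1, 11 without heterozygote replicate 6 and 11 without wild-type replicate 3. Striatum heterozygote replicate 1 stood apart in the choroid plexus and ependymal markers, at a mean log2 of 6.69 where the other 5 averaged 9.60.

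Across the 3 regions, 0 of the 14 list calls by camera held with an estimated correlation, and fry called only the MYT family in striatum. The exact permutation test of list means (2-sided) gave an unadjusted p under 0.05 for 1 list in striatum, the MYT family (p = 0.0043; adjusted p = 0.152), and for 0 lists in PFC and hippocampus. The list median, mean and camera direction differed in sign in 23 of 105 pairs of list and region, none of them called. When the libraries of a region were divided at random into groups of the same sizes, 90 of 100 splits in PFC, 95 in hippocampus and 74 in striatum called as many lists as the genotypes did. The other splits called a median of 6, 7 and 9 lists, against 4, 3 and 7 for the genotypes.

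**Figure D2:**
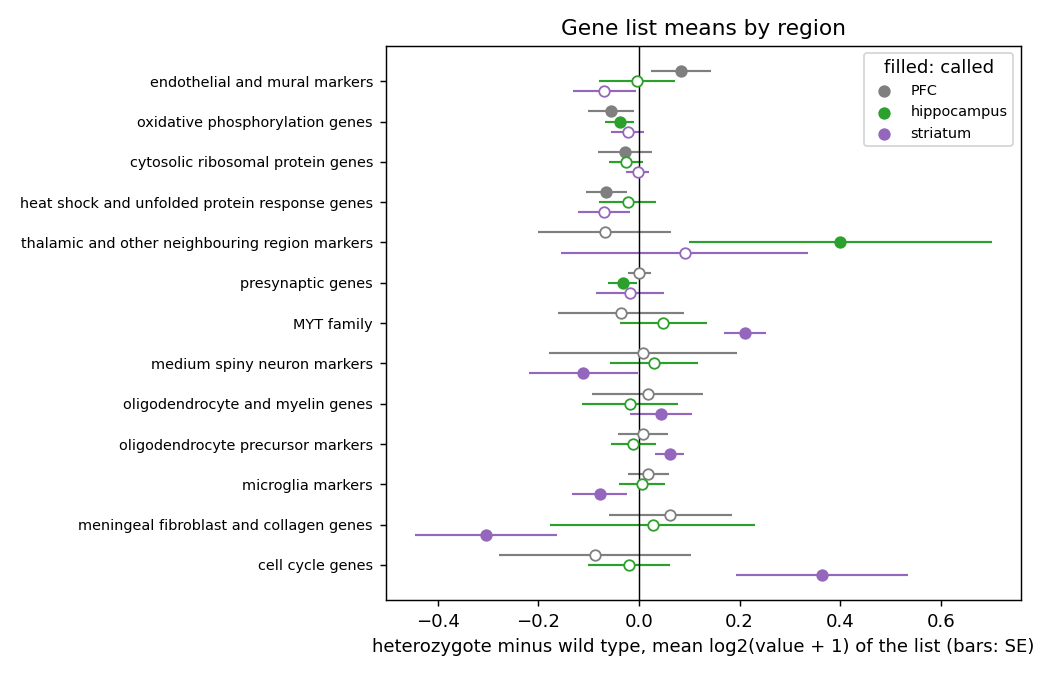
Heterozygote minus wild-type difference of the mean log2(value + 1) of 13 gene lists in each region (horizontal axis, log2 scale); points are differences, bars are the SE and filled points are lists called by camera with the preset correlation. In PFC 4 lists, in hippocampus 3 and in striatum 7 are filled, and 0 of these calls held with an estimated correlation.

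Medium spiny neuron, hippocampal and cortical markers were highest in striatum, hippocampus and PFC, in this order. Medium spiny neuron markers had a median of 4128 normalized counts over their gene means in wild-type striatum, 888 in PFC and 329 in hippocampus. Hippocampal region markers had a median of 1400 in wild-type hippocampus, 57.8 in PFC and 144 in striatum, and cortical region markers one of 1745 in PFC, 680 in hippocampus and 671 in striatum. Markers of thalamus and other neighbouring regions were highest in striatum, with medians of 819 there, 158 in hippocampus and 102 in PFC. Excitatory neuron markers stood at 2944 in PFC, 2948 in hippocampus and 446 in striatum; Slc17a7, a vesicular glutamate transporter, was at 3679 ± 3485 (SD, n = 6) in wild-type striatum, a spread nearly as wide as the mean. Choroid plexus and ependymal markers had medians of 261 in wild-type hippocampus and 327 in striatum and 13.4 in PFC. Ttr, the transthyretin of choroid plexus, was at 1591 in hippocampus heterozygote replicate 1, 1298 in hippocampus wild-type replicate 6 and 539 in striatum heterozygote replicate 1, while the other libraries of these regions were between 20035 and 81544.

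Whether the genotype effect differed between regions was tested as an interaction over 17051 genes. In limma, 0 genes passed for PFC against hippocampus (641 at an unadjusted p under 0.05), 0 for PFC against striatum (612) and 0 for hippocampus against striatum (629), where chance gives 853 for each. The model had no block for the column codes that recur across regions; with the code as a random block, 0, 0 and 0 passed and 698, 668 and 687 had an unadjusted p under 0.05. The smallest p belonged to Gpr149 and Nme7, Ogg1 and A930003O13Rik, and Npr1 and Kif15, in the order of these pairs. Ogg1, a DNA glycosylase of base excision repair, had log2 differences of -0.59 (SE 0.14) in PFC and 0.32 (SE 0.14) in striatum (adjusted p = 0.654 for the difference). Npr1, a natriuretic peptide receptor, had -0.56 (SE 0.14) in hippocampus and 0.31 (SE 0.13) in striatum. Nme7 had -0.23 (SE 0.09) in PFC and 0.29 (SE 0.09) in hippocampus.

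No gene was called in any region, so 0 called genes were shared where 0 would be shared by chance; in limma 29 higher and 49 lower genes had an unadjusted p under 0.05 in both PFC and hippocampus, 34 and 32 in both PFC and striatum, and 48 and 56 in both hippocampus and striatum, given without an expected number because the regions share column codes. Across genes, which are not independent replicates, the log2 differences of PFC and hippocampus had a Pearson correlation of 0.16, those of PFC and striatum 0.19 and those of hippocampus and striatum 0.19. When genotypes were reassigned over the column codes with the group sizes of each region kept, 7, 8 and 17 of 100 assignments gave a correlation as high.

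In a comparison added after seeing the data, the genotype effect averaged over the 3 regions, 16 of 17051 genes passed in limma, 8 of which rose and 8 fell, each with the same sign in the 3 regions. Selection by the mean of the 3 regions favours genes of the same sign, so this agreement is no separate support. The genes that rose include Srsf5, a splicing factor (0.12, SE 0.03), and Snrnp70 (0.13, SE 0.03), Rsrp1 (0.12, SE 0.02), Leng8 (0.14, SE 0.03) and Wsb1 (0.15, SE 0.03). Firre (0.17, SE 0.03), Ppox (0.20, SE 0.04) and the Y-linked translation factor gene Eif2s3y (0.23, SE 0.05) rose as well. The genes that fell include the respiratory chain genes Uqcrq (-0.21, SE 0.04) and Cox5b (-0.18, SE 0.04), the synaptic vesicle protein gene Tprgl (-0.11, SE 0.02), and Nptn (-0.19, SE 0.03). Gm1673 (-0.35, SE 0.07), Spryd7 (-0.16, SE 0.03) and Rnf11 (-0.10, SE 0.02) also fell. Tprgl had the smallest unadjusted p in limma and shared the smallest adjusted p, 0.0137, with other genes, among them Nptn and Rsrp1. Tprgl was at 3112 ± 64.9 (SD, n = 5) against 3340 ± 85.9 (SD, n = 6) in PFC. It was at 2872 ± 86.3 (SD, n = 5) against 3071 ± 139 (SD, n = 6) in hippocampus and 3095 ± 69.7 (SD, n = 6) against 3410 ± 125 (SD, n = 6) in striatum.

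The count of 16 depends on which libraries enter. Without the libraries whose code begins with 31 it was 40, 15 of them shared with the 16, and within those beginning with 35 it was 2, with 0 shared; the code beginning with 37 holds 1 library per group. It was 29 without the block, and leaving out 1 library gave 5 to 29.

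The 16th gene that passed, Hist2h2aa2, was singled out after its values were seen. It was listed at 0 in 3 of 5 PFC, 4 of 5 hippocampus and 4 of 6 striatum heterozygote libraries and in 0 of 18 wild-type libraries. The other heterozygote libraries were at 147 and 150 in PFC, 214 in hippocampus and 115 and 202 in striatum, and wild type spanned 129 to 164, 216 to 312 and 84.6 to 248 in these regions. The hippocampus library at 214 and the striatum library at 202 carry the code 31-67M, whose PFC library, labelled wild type, was at 142. The neighbour Hist2h2aa1 (chromosome 3, 96245497 to 96246082) has a transcript of 586 bases that contains the whole 528-base transcript of Hist2h2aa2 (chromosome 3, 96239749 to 96240276). The sum of the pair was 173 ± 31.9 (SD, n = 5) against 189 ± 24.2 (SD, n = 6) in PFC, 303 ± 46.3 (SD, n = 5) against 312 ± 35.1 (SD, n = 6) in hippocampus and 266 ± 59.4 (SD, n = 6) against 274 ± 15.7 (SD, n = 6) in striatum.

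**Figure D3:**
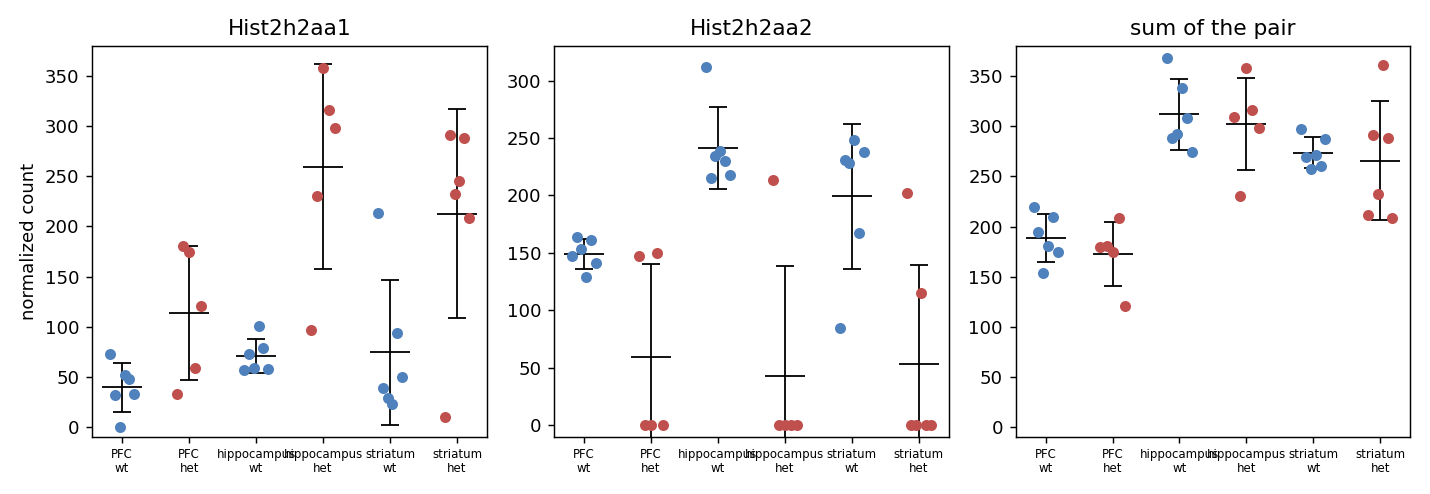
Normalized counts of Hist2h2aa1, Hist2h2aa2 and their sum (vertical axes) in each library by region and genotype; points are libraries, long bars are means and whiskers are the SD. Hist2h2aa2 is at 0 in heterozygote libraries only, while the sums of both genotypes overlap in each region.

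Regions were compared within wild type, also after seeing the data. Between PFC and hippocampus 7968 of 17051 genes differed, 3895 higher in PFC and 4073 higher in hippocampus. Between PFC and striatum 9723 differed (4745 and 4978), and between hippocampus and striatum 8173 (4070 and 4103). With equal library totals, which shift the median gene by -0.14 on the log2 scale for PFC against striatum, the counts were 8762 (2918 and 5844), 10528 (3195 and 7333) and 8369 (3367 and 5002). Genes higher than in both other regions numbered 2489 in PFC, 1576 in hippocampus and 2692 in striatum, of which 314, 261 and 647 were over 2-fold higher than in each. In PFC these included Cd6, a T cell surface protein, at 105 ± 30.7 (SD, n = 6) against 5.80 ± 3.59 in hippocampus and 5.24 ± 5.47 in striatum, and Myl4, a myosin light chain, at 706 ± 76.1 (SD, n = 6) against 36.5 ± 10.1 and 52.8 ± 37.6. In hippocampus they included Dsp, which encodes desmoplakin and marks dentate granule cells, at 1603 ± 120 (SD, n = 6) against 3.93 ± 3.77 in PFC and 47.7 ± 20.9 in striatum.

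Striatum-enriched genes included Isl1, a homeobox gene of striatal projection neurons, at 417 ± 44.3 normalized counts (SD, n = 6), and Six3 at 1401 ± 150 (SD, n = 6). Lhx8, a homeobox gene of basal forebrain cholinergic neurons, was at 270 ± 41.8 (SD, n = 6). Also among them were the hypothalamic neuropeptide genes Oxt, at 819 ± 398 (SD, n = 6), and Avp, at 260 ± 169 (SD, n = 6), and the hypothalamic homeobox gene Otp, at 136 ± 61.6 (SD, n = 6). Oxt, Avp and Otp were each under 2 in mean in PFC and hippocampus.

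**Figure D4:**
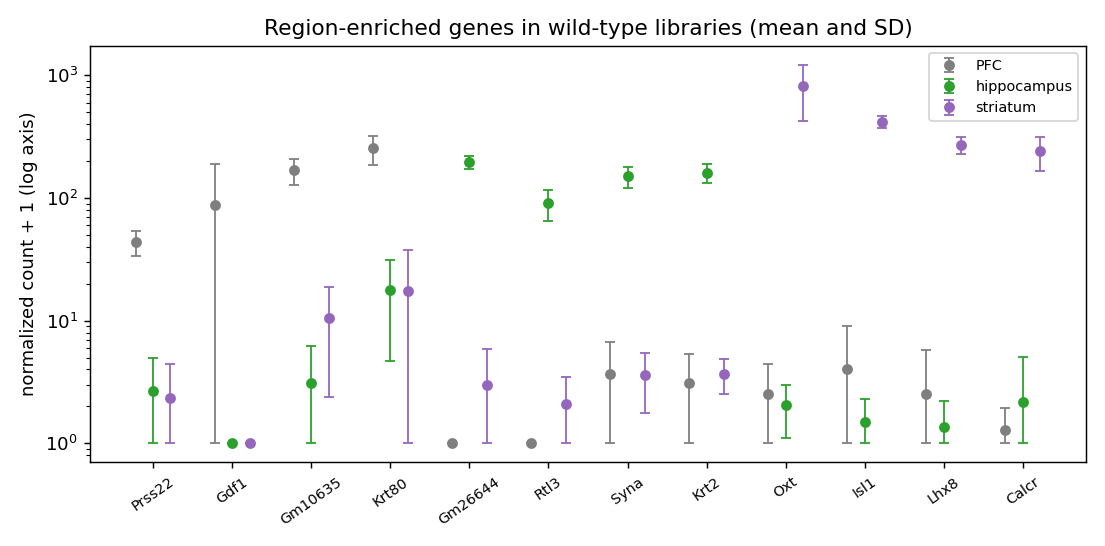
Mean normalized count plus 1 (vertical log axis) of 12 region-enriched genes in the wild-type libraries of each region (n = 6 per region); whiskers are the SD and end at 1 on the axis. Prss22 to Krt80 are highest in PFC, Gm26644 to Krt2 in hippocampus and Oxt to Calcr in striatum.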

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

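No test in this part was chosen after its result was seen: the rule, that the gap of the highest or lowest library to the nearest other exceeds a 95% critical share of the range of its group, was fixed for each named gene reported and each cell type list. Chance gives about 1 in 20 groups such a library, and 21 of 202 groups had one, 10 for genes and 11 for list means; genes and lists share libraries and are not independent. The cause was not tested for any of them.

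Among genes in PFC, Mycbpap was at 73.8 normalized counts in heterozygote replicate 5, where the other 4 averaged 40.5, Pltp at 1972 in heterozygote replicate 1 and Rps19 at 1895 in wild-type replicate 6. In striatum, Snrnp70 was at 10010 in heterozygote replicate 6, Ppp6c at 1499 and Myrf at 2926 in heterozygote replicate 3, Neu4 at 413.8 and Enpp6 at 457.3 in heterozygote replicate 1, Timm13 at 745.2 in wild-type replicate 3 and Hmgb2 at 204.3 in wild-type replicate 5.

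For list means (mean log2 of the members), the widest gaps were in the choroid plexus and ependymal markers, at 6.805 in hippocampus wild-type replicate 6, where the others averaged 8.96, and at 6.687 in striatum heterozygote replicate 1, where the others averaged 9.60. In hippocampus, blood cell genes were at 8.243 in wild-type replicate 6 and hippocampal region markers at 9.862 in wild-type replicate 2, and in striatum hippocampal region markers were at 7.507 in heterozygote replicate 5. In PFC heterozygotes, interneuron markers were at 10.37 in replicate 4, microglia markers at 9.482 in replicate 3 and endothelial and mural markers at 9.786 in replicate 1. In PFC wild type, astrocyte markers were at 12.5 in replicate 4, and replicate 1 was at 10.78 for oligodendrocyte and myelin genes and at 8.965 for meningeal fibroblast and collagen genes.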

How the results depend on the processing

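The alternatives on cohorts, and every alternative for the average over regions and for the wild-type regions, were chosen after seeing the data; the rest were planned, and the cause was not tested where a value differs. Under the other scalings, filters, pseudocounts and the fit of all libraries, the counts of genes in limma stayed at 0 in each region, except for 1 gene in hippocampus with equal library totals; the interaction counts stayed at 0 in every setting run, and the wild-type region counts stayed within 1.5 times. Against 0 genes in PFC there was 1 within cohort 35, and 0 to 2 with each library left out (2 without heterozygote replicate 2). Against 0 in hippocampus there was 1 with the cohort as a covariate, 6 without cohort 31, 2 within cohort 35, and 0 to 4 with each library left out (4 without heterozygote replicate 1, 2 without wild-type replicate 2, and 1 without wild-type replicate 3 or 6). Against 0 in striatum there was 1 without cohort 31, 2 within cohort 35, and 0 to 1 with each library left out (1 without heterozygote replicate 2). At the unadjusted p under 0.05, limma had 833, 1145 and 1004 genes.

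Of the lists called by camera (4, 3 and 7), 0, 0 and 0 were called with an estimated correlation and 0, 0 and 1 by fry. PFC had 8 within cohort 35 and 2 to 5 with each library left out (2 without heterozygote replicate 3 or 4 or wild-type replicate 2). Hippocampus had 5 without cohort 31, 5 within cohort 35, and 0 to 4 with each library left out (0 without wild-type replicate 6). Striatum had 5 to 13 (13 without heterozygote replicate 1, 11 without heterozygote replicate 6 or wild-type replicate 3). The PFC Myt1l level differed by -0.00543 (without wild-type replicate 1) to 0.0983 with each library left out, and the striatum Myt1l level by -0.0117 within cohort 35. Over pairs of a named gene and a setting, the threshold was lost in 119, gained in 13 and the sign reversed in 0. Only genes of the average over regions had passed, so the losses were theirs. Myt1l was counted apart, and its sign reversed in the 2 settings above. Over pairs of a called list and a setting, the call was lost in 68 and the direction reversed in 1. That one was the PFC list: cytosolic ribosomal protein genes, whose mean was -0.0647 (without wild-type replicate 6) to 0.0041 (without wild-type replicate 1) with each library left out; at 0.0041 it was not called.

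The average over regions gave 16 genes, and 29 with no block, 40 without cohort 31, 2 within cohort 35, and 5 to 29 with each library left out. With equal library totals it gave 18, 12 higher and 6 lower, against 8 and 8. It fell to 10, 8 and 5 without PFC heterozygote replicates 1, 3 and 5, to 6 without PFC wild-type replicate 2, to 10 and 5 without hippocampus heterozygote replicates 3 and 5, to 10 without striatum heterozygote replicate 6 and to 7 without striatum wild-type replicate 2. It was 27 without PFC heterozygote replicate 2, 29 without PFC wild-type replicate 1 and 26 without striatum heterozygote replicate 4.

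Replicate numbers were checked for pairing over the 2000 genes used. Libraries of the 2 genotypes with the same number correlated at -0.009 to 0.14 in PFC, -0.045 to 0.063 in hippocampus and -0.11 to 0.055 in striatum. The wild-type library of the same number was the best match of the heterozygote library in 2 of 5, 1 of 5 and 0 of 6 pairs. The numbers were therefore not taken as pairs. With the number as a block, 1 gene passed in hippocampus, Lbhd1 (log2 difference -1.27). That fit lacked wild-type replicate 6, and Lbhd1 also passed at -1.27 when only this library was left out. DESeq2 and limma-voom, both planned, were not run because the values are not whole counts. Surrogate variables, also planned, were not run either, although values that are not whole do not prevent it, so structure other than genotype was not modelled. The deposited table gives no reads, so the depth of a single value is known only by the estimate above.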

Other observations

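The splits for gene counts by region, the count without the Hist2h2aa pair, the neuron share test and both Hist2h2aa2 tests were chosen only after the result was seen, and the comparisons averaged over regions and within wild type were added after seeing the data; the other tests in this part were written before their results.

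Genes named in the average over regions had the same sign in PFC, hippocampus and striatum, which selection by that average favours, at different sizes. Nptn had log2 differences of -0.06, -0.30 and -0.23, Snrnp70 0.04, 0.11 and 0.23, and Srsf5 0.07, 0.12 and 0.18. Eif2s3y had 0.17, 0.29 and 0.24, and Gm1673 -0.43, -0.34 and -0.29. The interaction test passed 0 genes in limma, with 641, 612 and 629 at an unadjusted p under 0.05, fewer than the 853 that chance gives, so it did not show that any of these differs between regions or is alike in them.

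Random splits of the libraries test whether chance can be excluded. For the 0 genes of each region they cannot decide, because every split reaches a count of 0 (100, 100 and 100 of 100); other splits of PFC, hippocampus and striatum gave up to 21, 2 and 4 genes. The split with 21 genes may come from a structure of the PFC libraries other than genotype, which was not tested. For the gene lists chance cannot be excluded: 90, 95 and 74 of 100 splits called as many as the real 4, 3 and 7, with up to 15, 17 and 17 in others. For the interactions, at a real 0, the reassignments cannot decide for the same reason (100, 100 and 100 of 100), and others gave up to 1, 2 and 2. For the average over regions, 1 of 100 reassignments of genotype over the column codes, the real one, gave 16 genes, and the highest other gave 15. Every reassignment over the codes kept the group sizes of each region. This left the code 35-5M heterozygote and the PFC library of 31-67M wild type in each draw, so the set drawn from is restricted. With Hist2h2aa1 and Hist2h2aa2 left out of every count the real value was 15, and 2 of 100 gave as many, the highest other being 15 as well. Few of the 100 reassignments drawn reached the real count. The margin over the highest other was 1 gene with the pair and none without it. The count was 5 to 29 with each library left out and 2 within cohort 35, so chance is not firmly excluded. For the wild-type regions 1, 1 and 1 of 100 splits, the real ones, gave 7968, 9723 and 8173 genes, and the highest others gave 3654, 5775 and 4423, so chance is excluded.

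Oxidative phosphorylation genes were called lower in PFC and hippocampus by camera, but not with an estimated correlation (adjusted p = 0.974 and 0.994), nor in 1 of 11 PFC and 3 of 11 hippocampus fits that left out 1 library, nor in hippocampus with a replicate block (adjusted p = 0.178) or within cohort 35 (adjusted p = 0.461). After correction by length and GC class the list differences were -0.0456 (SE 0.0269) in PFC and -0.0388 (SE 0.0235) in hippocampus. These were 82.9% and 102% of those before, so the correction did not remove them. They lie within 2 of their standard errors of 0, so transcript length and GC content as the source is not decided. A lower share of neurons stays open, since excitatory marker minus list differences were 0.0676 (SE 0.0596) in PFC and -0.0073 (SE 0.0371) in hippocampus, within 2 of their standard errors. Chance was not excluded: 16 of 100 reassignments gave an average over regions as far from 0 as the real -0.038, with the highest other at 0.061. A genotype effect stays open and was not told apart from chance by this test.

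Hist2h2aa2 was at 0 in heterozygote libraries while its neighbour Hist2h2aa1 was high in them. Reads shared between this gene pair with a common transcript sequence may have moved between the entries. The log2 difference of the summed values farthest from 0 was -0.14 (PFC, SE 0.14), short of the 0.5 set as the bound. In wild type, Hist2h2aa1 was at 0 in PFC replicate 3, where Hist2h2aa2 was at 153. Striatum wild-type replicate 1 had Hist2h2aa1 at 213 and Hist2h2aa2 at 84.6. In the other wild-type libraries both were above 0 and Hist2h2aa2 was the higher. A kept sum does not say why Hist2h2aa2 was at 0 in heterozygote libraries only, so sharing alone is not shown as the cause. A variant carried by some of the animals would give each code the same state in all its heterozygote libraries, and 3 codes held both states. This does not exclude a variant, since the codes are not stated to mark animals. The code 31-67M, not one of these 3, stands on both genotypes, so a code may not mark 1 animal. A genotype effect on either gene was not tested apart from these.

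As a hypothesis, the rise of Srsf5 and Snrnp70 may belong to a broader rise of splicing factor genes in the heterozygotes. A list of 48 other splicing factor genes, drawn up without the genes already seen, had a mean log2 difference over the regions of 0.038, and 1 of 100 reassignments, the real one, was as far from 0; the highest other was 0.035. The difference between these values is small, the list was written after the pattern was seen, and the count of 16 genes it starts from was 2 within cohort 35. A difference between cohorts and a difference in RNA handling were not excluded.

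Oxytocin, vasopressin and Otp transcripts in striatum libraries could come from neighbouring hypothalamic or basal forebrain tissue in the dissection; no test was run that separates this from expression in striatum. Without cohort 31, the count for hippocampus against striatum in wild type was 7674 genes.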
